A study of Mus musculus with 24 samples.

How the data were processed

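The deposited data described hearts of C57BL/6 mice after sham surgery, 45 min of ischemia, or ischemia followed by 0.5, 1, 1.5, 3, 6 or 12 h of reperfusion, with 3 libraries in each of 8 groups. Per the labels' protocols, RNA was taken from flash-frozen heart tissue with Trizol and 1 ug of total RNA entered an Illumina TruSeq RNA kit. The group of every library came from its treatment label. The labels do not say that the 3 libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may in part be technical.

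Per the file headers, the authors deposited for every library whole-number read counts for 46078 Ensembl genes in 4 columns, with and without multiply mapped reads and with and without reads marked as duplicates, beside a column of RPKM. The column names are those that the R package dupRadar writes. The genome build was mm10, per the submitters' processing notes. The aligner, the marker of duplicates, the counter, its strand setting and the annotation release are not given in the sources used here. Because strand use is not stated, reads of overlapping or antisense genes, among them mt-Nd6 and the mitochondrial transfer RNA genes, are of uncertain origin. The main values were the deposited counts of uniquely mapped reads with duplicates kept. The RPKM values of the authors served only to recover the read total they were divided by, 18194893 to 21840469 reads per library.

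Unique counts summed to between 13407465 and 17181458 per library. Of them 39.2% to 54.5% were duplicates, 19.0% to 33.2% came from the 37 genes of the mitochondrial genome, and the 10 most abundant genes held 22.5% to 36.4%. Multiply mapped reads made up 12.8% to 20.1% of the totals that included them. A floor of 3 counts corresponded to 0.175 to 0.224 CPM per library. Reads without molecular identifiers are not independent molecules, so floors and intervals cover counting error only. Libraries of 1 group differed by a chi-square of 7.85 to 74.1 per degree of freedom over genes. The most alike of all pairs, 0.5 h replicate 3 and 1 h replicate 2, differed by 5.71, and 0 pairs were identical. Symbols came from the mouse gene name table for 45143 IDs (98.0%), and IDs without a symbol held at most 0.0502% of the counts of a library. Positions came from GENCODE vM21 on GRCm38, the assembly that mm10 names.

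Counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with Benjamini-Hochberg adjustment within each comparison, and a gene was called at an adjusted p under 0.05. All 24 libraries entered 1 fit with 1 coefficient per group, TMM factors (0.858 to 1.16) and no covariate, which left 16 residual degrees of freedom and a biological coefficient of variation of 0.156. The filter filterByExpr (minimum count 10, minimum total 15) kept 15128 genes, which held at least 99.9% of the counted reads. Every group was compared with sham (7 comparisons) and with the time before it (6 comparisons), and 1 test asked for a change across the 8 groups. Every adjusted p of a gene in the text is from this test unless another tool is named. Levels are CPM of the TMM-scaled library. A log2 fold change carries a standard error derived from the fitted model. Where the lower group had 1 to 3 reads over its 3 libraries, a ratio of CPM with an exact 95% interval replaced the fold change. A group with 0 reads was set at 3 reads over the group, which gives a lower bound.

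Before the data were examined, 37 lists of genes were fixed, 21 of pathways and 16 of cell types, together with the comparisons, the tests, the alternatives and the rule for naming genes. The pathway lists were immediate early genes, ferroptosis defence and promotion, inflammatory cytokines and adhesion, the interferon response, HIF and glycolysis, the heat shock response, the unfolded protein and integrated stress response, NRF2 targets, p53 targets, cell death executioners, Fanconi anaemia and crosslink repair, the cell cycle, fetal and wall stress genes, fatty acid oxidation, nuclear oxidative phosphorylation, mitochondrially encoded genes, cardiac ion channels and calcium handling, matrix remodelling, metallothionein with acute phase and glucocorticoid-induced genes, and the circadian clock. The cell type lists held markers of ventricular and atrial cardiomyocytes, endothelium, fibroblasts, smooth muscle and pericytes, neutrophils, monocytes, resident macrophages, T and NK cells, B cells, platelets, erythroid cells, mesothelium, fat, skeletal muscle and lung epithelium. Some genes stand in several lists. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over 245 tests of 35 lists in 7 comparisons, because the adipocyte and lung lists had only 1 and 2 tested genes. Of 109 tests called that way, 20 were also called with an estimated correlation.

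Genes were named by a fixed rule. For each comparison with sham it took the 8 largest rises and 4 largest falls among called genes with at least 5 CPM in the higher group, libraries that did not overlap and no predicted name. It added up to 4 called members of each list, 9 genes in every comparison (Atf3 and Fancd2 from the series title, Gpx4, Slc7a11, Ptgs2, Acsl4, Hmox1, Tfrc and Fth1), and 3 rises and 3 falls per step between neighbouring times. The result of 1 gene is not reported here. The alternatives were DESeq2 size factors, library totals, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 libraries, duplicates removed, multiply mapped reads included, mitochondrial genes left out, the replicate number as a block, only the 6 libraries compared, a minimum absolute log2 fold change of 1, each library left out in turn and, for lists, fry and an estimated correlation. A clock score (mean log2 CPM of Arntl and Npas2 minus that of Dbp and Per3) as covariate was added after the data were seen. Pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 under Python 3.11.15 were used for tables and plots.

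The procedure was tested on data simulated from 14484 genes of 3 h against sham, with 3 libraries per group and 50 changed genes per size. It recovered 26% of log2 changes of 0.585, 78% of 1, 96% of 2 and all 50 of 3, with 10 false calls. A list of 20 genes shifted by 0.5 had an adjusted p of 1.34e-08, and 0 of 30 unchanged lists were called. False calls among lists of correlated genes, or with as many changes as at 3 h, stay open. Simulating ischemia against sham without change gave 0 called genes.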

Results

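Messenger RNA was profiled in hearts of C57BL/6 mice, an inbred laboratory strain, by short-read sequencing. Hearts came from mice after sham surgery, after 45 min of ischemia, in which blood flow to the heart muscle is stopped, and after 45 min of ischemia followed by 0.5, 1, 1.5, 3, 6 or 12 h of reperfusion, in which flow returns. Each of the 8 groups held 3 libraries, 24 in all. Between 13407465 and 17181458 reads per library were counted in genes, and 15128 genes were tested. Expression is given in CPM (counts scaled to library size) as mean ± SD, changes as log2 fold changes ± SE, and n was 3 in every group.

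Libraries of 3, 6 and 12 h lay apart from each other and from the rest on the principal components of log2 CPM, of which component 1 held 35.5% of the variance and component 2 17.3%. Those of 1 h overlapped with 0.5 h and with 1.5 h, and ischemia replicate 1 lay beside sham, at -35.6 on component 1. Sham libraries lay between -38.1 and -32.5 on component 1, libraries of 6 h between 57.6 and 85.6, and those of 12 h between 40.6 and 49.6. Ischemia replicate 3 lay at 0.356 on component 2, apart from ischemia replicates 1 and 2 at -28.7 and -21.4 and within the range of the 0.5 h libraries (-8.19 to 12.6).

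**Figure D1:**
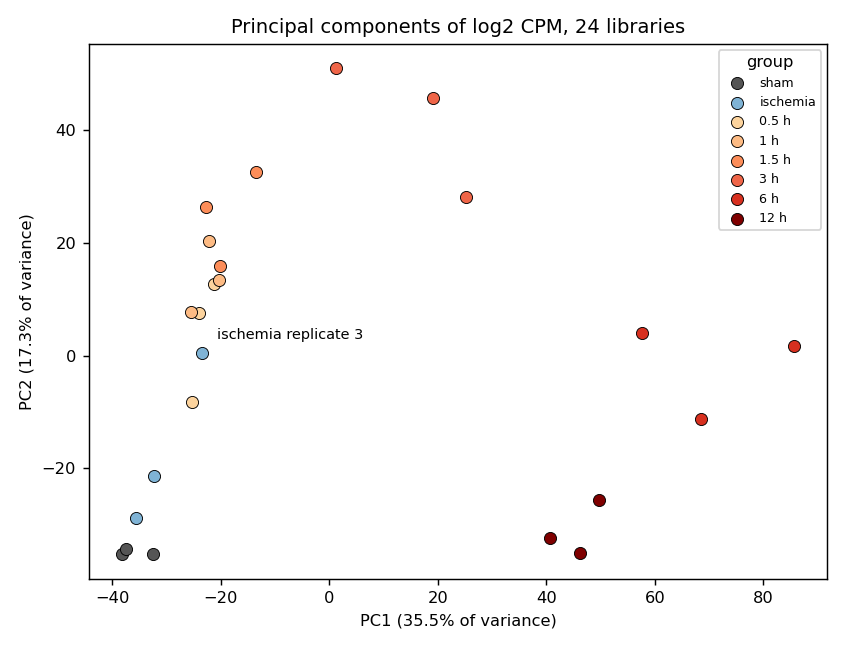
Principal components of log2 CPM for 24 libraries, with component 1 (35.5% of variance) on the x axis, component 2 (17.3%) on the y axis, 1 point per library and colour for the group. Libraries of 6 h lie farthest to the right, from 57.6 to 85.6 on component 1, and ischemia replicate 3 lies at 0.356 on component 2, near the 0.5 h libraries.

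Ischemia against sham addressed what 45 min without flow changed before reperfusion. Some immediate early transcription factors and chemokines were higher. Fosb, a subunit of the AP-1 transcription factor, rose from 1.03 ± 0.254 to 74.3 ± 39.3 CPM (log2 fold change 6.19 ± 0.80, adjusted p = 0.000415). The related subunit Fos rose from 12.0 ± 6.55 to 142 ± 30.9 CPM (3.58 ± 0.46, adjusted p = 0.000415). The neutrophil chemokines Cxcl2 (4.17 ± 0.60) and Cxcl1 (2.34 ± 0.40), the prostaglandin synthase Ptgs2 (3.31 ± 0.47), the AP-1 subunit Junb (2.60 ± 0.40) and the NF-kappaB regulator Nfkbiz (1.88 ± 0.36) rose as well. Atf3, a stress-induced transcription factor of the ATF/CREB family, rose by 2.80 ± 0.53 (adjusted p = 0.0266).

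Of the immediate early genes, 6 of 34 tested members rose and 0 fell (25 and 0 adjusted over the list alone), with a median of 1.23 (camera adjusted p = 1.65e-42, and adjusted p = 0.0404 with an estimated correlation). Among inflammatory cytokines and adhesion molecules, 5 rose, 0 fell and 22 were not called (14 and 0 adjusted over the list alone). The median was 1.11 (camera adjusted p = 1.01e-24, and adjusted p = 0.0345 with an estimated correlation). Il6 had 151 reads against 1, a ratio of 145 with a 95% exact counting interval from 25.6 to 5765. In the unfolded protein and integrated stress response, the median was 0.41 (camera adjusted p = 1.14e-09, and adjusted p = 0.0646 with an estimated correlation), and 0 of 23 were called higher and 0 lower (10 and 0 adjusted over the list alone). Of the neutrophil markers, 0 of 14 tested members rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 1.73 (camera adjusted p = 1.43e-12, and adjusted p = 0.0847 with an estimated correlation). Erythroid markers, with 0 members called, had a median of 1.20 (camera adjusted p = 6.34e-08, and adjusted p = 0.111 with an estimated correlation). Lists of monocytes, resident macrophages, fibroblasts, B cells and atrial cardiomyocytes were called too, with medians of 0.37, 0.20, 0.19, 0.37 and 0.21 and again 0 called members, and lost the call with an estimated correlation (adjusted p = 0.317, 0.248, 0.501, 0.314 and 0.221). The first 4 were also lost without ischemia replicate 1 (adjusted p = 0.0773, 0.121, 0.165 and 0.2999), B cells without sham replicate 1 (adjusted p = 0.528) and atrial markers without sham replicate 3 or ischemia replicates 2 or 3 (adjusted p = 0.170, 0.0625 and 0.0687). In the order given, adjusted p ran from 0.000159 to 0.317, from 0.000734 to 0.248, from 0.00597 to 0.501, from 0.000316 to 0.528 and from 0.00952 to 0.221 over the alternatives. The lists of the cell cycle, matrix remodelling, cardiac ion channels and calcium handling, nuclear oxidative phosphorylation, fetal and wall stress, fatty acid oxidation and p53 targets were called likewise, with medians of 0.55, 0.29, -0.18, 0.067, 0.13, -0.10 and 0.16 and 0 called members, and lost the call with an estimated correlation (adjusted p = 0.407, 0.232, 0.445, 0.689, 0.476, 0.540 and 0.123). Without ischemia replicate 3, nuclear oxidative phosphorylation was lost (adjusted p = 0.129, from 0.000146 to 0.689 over its alternatives), as were fetal genes there or without sham replicate 3 (adjusted p = 0.113 and 0.125, from 0.000925 to 0.476) and p53 targets there or without sham replicate 2 (adjusted p = 0.0604 and 0.0960, from 0.00811 to 0.123). Fatty acid oxidation was lost without sham or ischemia replicate 1 (adjusted p = 0.124 and 0.124, from 0.00461 to 0.540). Of the mitochondrially encoded protein genes, 0 rose, 0 fell and 13 were not called (0 and 2 adjusted over the list alone). The median was -0.25 (camera adjusted p = 0.000724, and adjusted p = 0.311 with an estimated correlation). The share of counted reads from the mitochondrial genome was 31.0% ± 2.14 in sham and 26.3% ± 6.32 in ischemia, where replicate 3 had 19.0%.

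In all, 14 genes were higher and 0 were lower in ischemia by edgeR, where 1296 genes had an unadjusted p under 0.05. DESeq2 called 40 higher and 8 lower, and limma-voom called 3 higher and 0 lower. Without a filter 289 genes were called, and 29 with only these 6 libraries. The count depended on single libraries, with 5 without sham replicate 1, 5 without sham replicate 2, 7 without sham replicate 3, 39 without ischemia replicate 1 and 9 without ischemia replicate 3. The call of Atf3 was lost without sham replicates 1, 2 or 3 or ischemia replicate 3 (adjusted p = 0.154, 0.179, 0.177 and 0.208), that of Junb without sham replicates 1 or 2 (adjusted p = 0.0757 and 0.0641), that of Cxcl1 without sham replicates 1 or 2 (adjusted p = 0.116 and 0.152), that of Nfkbiz without sham replicates 1 or 2 or ischemia replicate 3 (adjusted p = 0.222, 0.179 and 0.317) and that of Il6 without sham replicates 1, 2 or 3 (adjusted p = 0.112, 0.0915 and 0.0729). Over the alternatives, adjusted p ran from 5.96e-63 to 0.256 for Atf3, from 1.11e-57 to 0.0757 for Junb, from 9.03e-31 to 0.192 for Cxcl1, from 5.66e-28 to 0.317 for Nfkbiz and from 9.03e-31 to 0.450 for Il6. Fosb, Cxcl2 and Ptgs2 were called without each library in turn and lost with limma-voom (adjusted p from 1.15e-185 to 0.399, 9.25e-34 to 0.379 and 3.34e-41 to 0.179 over their alternatives).

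At 0.5 h of reperfusion, against sham, most tested immediate early and cytokine genes rose, as did 7 of 18 heat shock genes. Hspa1a and Hspa1b, neighbouring copies that encode the inducible HSP70 chaperone, rose by 7.18 ± 0.87 and 7.35 ± 0.97, from 1.60 ± 1.25 to 242 ± 279.8 CPM and from 1.89 ± 1.40 to 311 ± 369 CPM. Since only 66.4% and 72.9% of their reads mapped to a single place, the split between the copies is uncertain. Fosb (7.86 ± 0.82), Fos (5.45 ± 0.50), Cxcl2 (4.95 ± 0.58), Atf3 (4.75 ± 0.56), Socs3, an inhibitor of cytokine signalling (4.67 ± 0.57), and Junb (4.50 ± 0.43) rose. Among the largest falls were the long noncoding RNA AI480526 (-2.01 ± 0.31) and the mitochondrial transfer RNA genes mt-Ts2 (-1.90 ± 0.29) and mt-Ti (-1.86 ± 0.34).

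Among immediate early genes, the median was 2.25 (camera adjusted p = 4.17e-52, and adjusted p = 0.0345 with an estimated correlation), and 32 of 34 were called higher and 0 lower (33 and 0 adjusted over the list alone). Among cytokines and adhesion molecules, 18 of 27 tested members rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 2.19 (camera adjusted p = 4.96e-23, and adjusted p = 0.0371 with an estimated correlation). Il6 had 210 reads against 1, a ratio of 199 with a 95% exact counting interval from 35.4 to 7903, and Ccl3 had 113 reads against 1, a ratio of 107 with a 95% exact counting interval from 18.8 to 4269.9. Of the neutrophil markers, 5 rose, 0 fell and 9 were not called (7 and 0 adjusted over the list alone). The median was 1.50 (camera adjusted p = 3.19e-05, and adjusted p = 0.363 with an estimated correlation). In the heat shock response, the median was 0.34 (camera adjusted p = 3.36e-05, and adjusted p = 0.367 with an estimated correlation), and 7 of 18 were called higher and 0 lower (7 and 0 adjusted over the list alone). Dnajb1, a co-chaperone, rose by 2.87 ± 0.56. Of the p53 targets, 8 of 16 tested members rose and 0 fell (8 and 1 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.0149, and adjusted p = 0.103 with an estimated correlation). Btg2 (2.98 ± 0.43) was the largest rise. Of the nuclear genes of oxidative phosphorylation, 8 rose, 0 fell and 22 were not called (13 and 0 adjusted over the list alone). The median was 0.20 (camera adjusted p = 3.20e-05, and adjusted p = 0.557 with an estimated correlation). Ndufb8, a complex I subunit, rose by 1.30 ± 0.22. Of the ventricular cardiomyocyte markers, the median was 0.19 (camera adjusted p = 0.0290, and adjusted p = 0.592 with an estimated correlation), and 3 of 17 were called higher and 0 lower (3 and 0 adjusted over the list alone). The list was no longer called without sham replicate 3 and without 0.5 h replicate 1 (adjusted p = 0.0528 and 0.0672, from 3.68e-05 to 0.592 over its alternatives). Of the mitochondrially encoded protein genes, 0 of 13 tested members rose and 8 fell (0 and 8 adjusted over the list alone), with a median of -0.57 (camera adjusted p = 0.000795, and adjusted p = 0.311 with an estimated correlation). The list was no longer called with duplicate reads removed (adjusted p = 0.436, from 6.90e-06 to 0.436 over its alternatives). mt-Nd6 (-1.15 ± 0.25) and mt-Nd2 (-1.02 ± 0.21) fell most, as the mitochondrial share of reads stood at 21.2% ± 1.16 against 31.0% ± 2.14 in sham, and mt-Nd2 was no longer called with duplicate reads removed, a setting that brought the median of the 13 genes to -0.090. Of the erythroid markers, 3 rose, 0 fell and 4 were not called (3 and 0 adjusted over the list alone). The median was 0.92 (camera adjusted p = 0.00812, and adjusted p = 0.476 with an estimated correlation).

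At 0.5 h, 1124 genes were higher and 678 lower than in sham, 326 and 116 of them by at least 2-fold. Scaled by library totals alone, 1629 were higher and 230 lower (87.6% against 62.4% higher), with the median of all genes shifted by 0.128. The count was 766 without sham replicate 1, 904 without sham replicate 2, 664 without sham replicate 3, 603 without 0.5 h replicate 1, 1093 without 0.5 h replicate 2 and 771 without 0.5 h replicate 3.

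Compared directly with ischemia, Hspa1b (7.17 ± 0.95, adjusted p = 0.000619), Hspa1a (6.21 ± 0.80, adjusted p = 0.000619) and the AP-1 subunit Jun (2.15 ± 0.35, adjusted p = 0.0106) were higher at 0.5 h of reperfusion. These were among 5 genes higher and 0 lower by edgeR, with 1871 genes at an unadjusted p under 0.05, 44 higher and 18 lower by DESeq2 and 4 higher and 0 lower by limma-voom. Without a filter 329 were called. The count was 2 without ischemia replicate 1, 2 without ischemia replicate 2, 1156 without ischemia replicate 3, 40 without 0.5 h replicate 2 and 2 without 0.5 h replicate 3. The call of Jun was lost without ischemia replicates 1 or 2 or 0.5 h replicate 3 (adjusted p = 0.246, 0.154 and 0.180). Its adjusted p ran from 1.18e-43 to 0.252 over the alternatives. Fitted with the 6 libraries of both groups alone, 0 genes were called, and Hspa1a and Hspa1b had adjusted p from 1.81e-234 to 0.120 and from 5.86e-279 to 0.120 over their alternatives.

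After 1 h of reperfusion, most cytokine and immediate early genes were high, with 7 of 18 heat shock and 6 of 22 matrix genes. Il6 had 577 reads against 1, a ratio of 550.1 with a 95% exact counting interval from 98.4 to 21767 (Il6 encodes interleukin 6). Fosb (8.99 ± 0.85), Hspa1b (7.93 ± 0.98), Hspa1a (7.82 ± 0.88), Fos (6.08 ± 0.51), Atf3 (5.78 ± 0.58, from 8.47 ± 0.389 to 466 ± 98.9 CPM) and Socs3 (5.55 ± 0.58) rose. Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, fell by 4.92 ± 1.23, followed by Atcay (-2.84 ± 0.69), AI480526 (-2.33 ± 0.32) and mt-Ts2 (-1.96 ± 0.29).

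In the immediate early list, the median was 2.68 (camera adjusted p = 7.56e-75, and adjusted p = 0.0164 with an estimated correlation), and 32 of 34 were called higher and 0 lower (32 and 0 adjusted over the list alone). Among cytokine and adhesion genes, 19 of 27 tested members rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 3.22 (camera adjusted p = 4.93e-32, and adjusted p = 0.0210 with an estimated correlation). Of the neutrophil markers, 6 rose, 0 fell and 8 were not called (8 and 0 adjusted over the list alone). The median was 1.21 (camera adjusted p = 2.21e-05, and adjusted p = 0.354 with an estimated correlation). In the heat shock response, the median was 0.42 (camera adjusted p = 3.37e-08, and adjusted p = 0.213 with an estimated correlation), and 7 of 18 were called higher and 0 lower (11 and 0 adjusted over the list alone). Among genes of ferroptosis defence, 3 of 21 tested members rose and 0 fell (3 and 0 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 0.00657, and adjusted p = 0.365 with an estimated correlation). These were the small heat shock protein Hspb1 (2.11 ± 0.25, in the heat shock list too), the ferritin light chain Ftl1 (1.08 ± 0.20) and the cystine transporter subunit Slc3a2 (0.80 ± 0.17). Of the matrix remodelling genes, 6 rose, 0 fell and 16 were not called (8 and 0 adjusted over the list alone). The median was 0.43 (camera adjusted p = 1.37e-06, and adjusted p = 0.181 with an estimated correlation). The protease Adamts1 rose by 2.39 ± 0.38. Of the nuclear oxidative phosphorylation genes, the median was 0.33 (camera adjusted p = 9.23e-07, and adjusted p = 0.501 with an estimated correlation), and 10 of 30 were called higher and 0 lower (15 and 0 adjusted over the list alone). Ndufb8 (1.16 ± 0.22) and Cox8b (0.94 ± 0.19) led. Of the p53 targets, 5 of 16 tested members rose and 0 fell (7 and 1 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.00223, and adjusted p = 0.0427 with an estimated correlation).

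At 1 h, 1129 genes were higher and 516 lower than in sham. Scaled by library totals, 1162 were higher and 261 lower (81.7% against 68.6% higher). The count was 751 without sham replicate 1, 867 without sham replicate 2, 942 without sham replicate 3 and 559 without 1 h replicate 1. The call of Cyp1a1 was lost without sham replicate 2 or 1 h replicate 1 (adjusted p = 0.0974 and 0.0574). The range of its adjusted p was from 1.61e-47 to 0.208 over the alternatives. Between 0.5 h and 1 h, edgeR called 0 genes, DESeq2 0 and limma-voom 0, while 1003 genes had an unadjusted p under 0.05 and 2221 had libraries that did not overlap (14.7%, with 10% by chance). Without a filter 159 were called, a setting whose small adjusted p need not measure the spread between libraries. Leaving out 0.5 h replicate 3 gave 3 calls.

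By 1.5 h of reperfusion, Fosb had risen to 849 ± 257 CPM (9.70 ± 0.86), and the rise of the soluble pattern recognition protein Ptx3 (6.34 ± 0.62) and of Socs3 (6.71 ± 0.60) placed both among the largest. Il6 had 1054 reads against 1, a ratio of 984 with a 95% exact counting interval from 176 to 38899. Hspa1b (8.44 ± 1.00), Hspa1a (8.13 ± 0.89) and Fos (6.17 ± 0.51) completed the leading rises against sham. AI480526 (-2.40 ± 0.33) and the apelin receptor Aplnr (-1.92 ± 0.44) were among the largest falls.

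For immediate early genes, 32 rose, 0 fell and 2 were not called (34 and 0 adjusted over the list alone). The median was 2.82 (camera adjusted p = 3.20e-89, and adjusted p = 0.0105 with an estimated correlation). Among cytokines and adhesion molecules, the median was 3.33 (camera adjusted p = 3.76e-46, and adjusted p = 0.0105 with an estimated correlation), and 20 of 27 were called higher and 0 lower (21 and 0 adjusted over the list alone). Within the heat shock response, 10 of 18 tested members rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.56 (camera adjusted p = 1.07e-17, and adjusted p = 0.0442 with an estimated correlation). Dnajb1 (4.69 ± 0.59) followed the HSP70 copies. Of the metallothionein, acute phase and glucocorticoid-induced genes, 6 rose, 0 fell and 11 were not called (10 and 0 adjusted over the list alone). The median was 1.21 (camera adjusted p = 9.07e-08, and adjusted p = 0.0956 with an estimated correlation). Mt2, a metal-binding metallothionein, rose by 2.73 ± 0.38 and the iron-siderophore binder Lcn2 by 2.31 ± 0.44. Of the matrix remodelling genes, the median was 0.58 (camera adjusted p = 2.88e-11, and adjusted p = 0.0617 with an estimated correlation), and 8 of 22 were called higher and 0 lower (9 and 0 adjusted over the list alone). Thbs1 (3.30 ± 0.38) and Adamts4 (3.20 ± 0.47) were examples. Of the neutrophil markers, 10 of 14 tested members rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 2.06 (camera adjusted p = 6.34e-11, and adjusted p = 0.111 with an estimated correlation). Il1r2 had 88 reads against 2, a ratio of 41.1 with a 95% exact counting interval from 11.04 to 344. Of the p53 targets, 5 rose, 0 fell and 11 were not called (5 and 0 adjusted over the list alone). The median was 0.28 (camera adjusted p = 0.00119, and adjusted p = 0.0371 with an estimated correlation). Of the fetal and wall stress genes, the median was 0.45 (camera adjusted p = 0.00193, and adjusted p = 0.363 with an estimated correlation), and 4 of 13 were called higher and 0 lower (5 and 0 adjusted over the list alone). Xirp1 (1.87 ± 0.30) and the natriuretic peptide Nppb (1.74 ± 0.38) led.

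At 1.5 h, 689 genes were higher and 452 lower than in sham. The count was 683 without sham replicate 1, 655 without sham replicate 2, 670 without sham replicate 3, 665 without 1.5 h replicate 1 and 503 without 1.5 h replicate 3. From 1 h to 1.5 h, 8 genes were higher and 2 lower by edgeR, against 55 and 15 by DESeq2 and 1 and 1 by limma-voom, and the leading rises were the leukocyte adhesion molecule Selp (3.11 ± 0.43), the transcription factor Ikzf4 (2.52 ± 0.45) and the lubricating proteoglycan Prg4 (1.58 ± 0.24). The count was 0 without 1 h replicate 1, 2 without 1 h replicate 3, 20 without 1.5 h replicate 1 and 6 without 1.5 h replicate 3. The call of Selp was lost without 1 h replicate 1 (adjusted p = 0.0535), that of Ikzf4 without 1 h replicates 1, 2 or 3 or 1.5 h replicate 3 (adjusted p = 0.0933, 0.0839, 0.130 and 0.470) and that of Prg4 without 1 h replicate 1 (adjusted p = 0.0772). Over the alternatives, adjusted p ran from 1.70e-20 to 0.0898 for Selp, from 4.69e-13 to 0.470 for Ikzf4 and from 6.83e-17 to 0.114 for Prg4.

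At 3 h against sham, most cytokine genes were high, as were 13 of 18 heat shock and 13 of 23 stress response genes, although both of those lists lost the call with an estimated correlation. Il6 had 812 reads against 1, a ratio of 756 with a 95% exact counting interval from 135 to 29878. Cxcl5 had 618 reads against 3, a ratio of 192 with a 95% exact counting interval from 65.3 to 932, and Csf3 had 230 reads against 1, a ratio of 214 with a 95% exact counting interval from 38.0 to 8489. Fosb (9.16 ± 0.85), Hspa1b (8.45 ± 1.00), Ptx3 (8.11 ± 0.61) and Hspa1a (8.01 ± 0.89) rose as well. Atcay (-3.45 ± 0.73), the chemokine receptor Cx3cr1 (-3.02 ± 0.52), the lipid hydrolase Pnpla3 (-2.77 ± 0.52) and the zinc finger gene Zfp113 (-2.73 ± 0.34) fell most.

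Within the immediate early list, 33 of 34 tested members rose and 0 fell (33 and 0 adjusted over the list alone), with a median of 2.60 (camera adjusted p = 1.27e-31, and adjusted p = 0.0646 with an estimated correlation). Among cytokines and adhesion molecules, 24 rose, 0 fell and 3 were not called (25 and 0 adjusted over the list alone). The median was 4.06 (camera adjusted p = 6.13e-27, and adjusted p = 0.0338 with an estimated correlation). For the unfolded protein and integrated stress response, the median was 0.66 (camera adjusted p = 3.89e-07, and adjusted p = 0.123 with an estimated correlation), and 13 of 23 were called higher and 0 lower (14 and 0 adjusted over the list alone). Ppp1r15a, which directs dephosphorylation of eIF2alpha, rose by 3.09 ± 0.32 and the transcription factor Atf4 by 2.22 ± 0.20. Of the NRF2 targets, 6 of 16 tested members rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.0125, and adjusted p = 0.455 with an estimated correlation). Heme oxygenase Hmox1 (4.04 ± 0.47), the cystine transporter Slc7a11 (2.88 ± 0.61, with 9 reads in sham) and thioredoxin reductase Txnrd1 (1.73 ± 0.14) led. Of the matrix remodelling genes, 16 rose, 0 fell and 6 were not called (18 and 0 adjusted over the list alone). The median was 1.33 (camera adjusted p = 4.04e-13, and adjusted p = 0.0427 with an estimated correlation). Adamts4 (4.29 ± 0.48) and the urokinase receptor Plaur (3.74 ± 0.39) were examples. Of the fetal and wall stress genes, the median was 1.47 (camera adjusted p = 1.28e-06, and adjusted p = 0.111 with an estimated correlation), and 9 of 13 were called higher and 1 lower (9 and 1 adjusted over the list alone). Of the HIF and glycolysis genes, 11 of 25 tested members rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.00812, and adjusted p = 0.365 with an estimated correlation). Pfkfb3, an activator of glycolysis, rose by 2.24 ± 0.35.

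In the heat shock response at 3 h, 13 rose, 1 fell and 4 were not called (14 and 1 adjusted over the list alone). The median was 0.73 (camera adjusted p = 2.98e-07, and adjusted p = 0.248 with an estimated correlation). Of metallothionein, acute phase and glucocorticoid-induced genes, the median was 2.04 (camera adjusted p = 2.24e-08, and adjusted p = 0.0848 with an estimated correlation), and 13 of 17 were called higher and 0 lower (14 and 0 adjusted over the list alone). Mt2 (4.23 ± 0.40) and Lcn2 (3.60 ± 0.44) rose. Serpina3m had 16 reads against 0, at least 4.96-fold higher with a floor of 3 reads over the group, a bound at which the median of the list stayed the same. Among cell death executioners and their regulators, 7 of 22 tested members rose and 2 fell (8 and 2 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.0214, and adjusted p = 0.447 with an estimated correlation). The list was no longer called without 3 h replicate 1 (adjusted p = 0.130, from 0.00249 to 0.447 over its alternatives). The inflammasome sensor Nlrp3 (2.63 ± 0.52), the inflammatory caspase Casp4 (2.14 ± 0.29) and the kinase Ripk1 (1.88 ± 0.22) were the largest. Of the neutrophil markers, 12 rose, 0 fell and 2 were not called (13 and 0 adjusted over the list alone). The median was 2.75 (camera adjusted p = 1.89e-07, and adjusted p = 0.248 with an estimated correlation). Of the resident macrophage markers, the median was 0.035 (camera adjusted p = 0.421), with median, mean and test differing in sign, and 2 of 15 were called higher and 4 lower (2 and 4 adjusted over the list alone). Cx3cr1 and Adgre1 (-0.89 ± 0.14) fell, and the hyaluronan receptor Lyve1 rose (0.68 ± 0.16). Of the Fanconi anaemia and crosslink repair genes, 0 of 17 tested members rose and 5 fell (0 and 5 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 0.122). Fan1, a nuclease, fell by 1.04 ± 0.31.

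In total 2785 genes were higher and 2556 lower at 3 h than in sham, 1070 and 776 by at least 2-fold. From 1.5 h to 3 h, 811 genes were higher and 479 lower. Cxcl5 (3.18 ± 0.38), the SH2 domain gene Sh2d5 (2.72 ± 0.45) and Prg4 (2.61 ± 0.21) had the largest rises, and Jun (-1.77 ± 0.35) was among the largest falls. The count was 620 without 1.5 h replicate 1, 525 without 1.5 h replicate 2, 700 without 3 h replicate 1 and 534 without 3 h replicate 3.

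At 6 h of reperfusion the largest number of genes differed from sham, with 26 of 27 cytokine and adhesion genes and 20 of 22 matrix genes above sham and 12 of 20 cardiac ion channel and calcium handling genes below. Cxcl5 had 5716 reads against 3, a ratio of 1704 with a 95% exact counting interval from 583 to 8263. Cxcl3 had 815 reads against 1, a ratio of 729 with a 95% exact counting interval from 130.4 to 28815, and Il6 had 689 reads against 1, a ratio of 616 with a 95% exact counting interval from 110.2 to 24366. Saa3 had 1169 reads against 2, a ratio of 523 with a 95% exact counting interval from 144 to 4320.1 (an acute phase apolipoprotein), and Mmp8 had 555 reads against 1, a ratio of 496 with a 95% exact counting interval from 88.7 to 19634 (neutrophil collagenase). Ptx3 rose by 8.43 ± 0.61. The extracellular matrix gene Spon2 (-4.88 ± 0.93), the muscle gene Ky (-4.84 ± 0.33), the indole methyltransferase Inmt (-3.87 ± 0.45) and the DNA demethylase Tet1 (-3.50 ± 0.36) had the largest falls.

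Among cytokine and adhesion genes, 26 rose, 0 fell and 1 was not called (26 and 0 adjusted over the list alone). The median was 5.38 (camera adjusted p = 1.12e-23, and adjusted p = 0.0371 with an estimated correlation). Of the matrix remodelling genes, the median was 2.46 (camera adjusted p = 6.85e-15, and adjusted p = 0.0371 with an estimated correlation), and 20 of 22 were called higher and 0 lower (20 and 0 adjusted over the list alone). The metalloproteinase inhibitor Timp1 rose by 5.08 ± 0.33. Of the fetal and wall stress genes, 11 of 13 tested members rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 2.69 (camera adjusted p = 5.74e-11, and adjusted p = 0.0427 with an estimated correlation). The cytokine receptor Tnfrsf12a (4.33 ± 0.33), the actin cross-linker Flnc (4.12 ± 0.43) and Nppb (3.93 ± 0.41) led. Of the NRF2 targets, 10 rose, 3 fell and 3 were not called (10 and 4 adjusted over the list alone). The median was 0.79 (camera adjusted p = 0.00479, and adjusted p = 0.404 with an estimated correlation). Of metallothionein, acute phase and glucocorticoid-induced genes, the median was 2.89 (camera adjusted p = 9.23e-07, and adjusted p = 0.130 with an estimated correlation), and 11 of 17 were called higher and 2 lower (11 and 2 adjusted over the list alone). Serpina3m was at least 8.94-fold above sham, and at that bound the median stayed the same. Of the cardiac ion channel and calcium handling genes, 1 of 20 tested members rose and 12 fell (1 and 12 adjusted over the list alone), with a median of -0.58 (camera adjusted p = 0.000132, and adjusted p = 0.240 with an estimated correlation). The potassium channel genes Kcnj3 (-2.88 ± 0.20) and Kcnj2 (-1.99 ± 0.23) and the SERCA inhibitor Pln (-1.32 ± 0.17) fell most. Of the mitochondrially encoded protein genes, 0 rose, 7 fell and 6 were not called (0 and 7 adjusted over the list alone). The median was -0.54 (camera adjusted p = 0.126). The list was called scaled by library totals (adjusted p = 0.0415, from 0.0316 to 0.773 over its alternatives). The mitochondrial share of reads was 19.0% to 21.3% in the 3 libraries, and with duplicate reads removed the median of these genes was -0.041.

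Of the immediate early genes at 6 h, the median was 1.78 (camera adjusted p = 1.28e-10, and adjusted p = 0.367 with an estimated correlation), and 28 of 34 were called higher and 0 lower (28 and 0 adjusted over the list alone). Arc (5.44 ± 0.70) and Egr3 (4.63 ± 0.56) led. In the heat shock response, 12 of 18 tested members rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 0.000240, and adjusted p = 0.442 with an estimated correlation). Of the unfolded protein and integrated stress response genes, 15 rose, 2 fell and 6 were not called (16 and 2 adjusted over the list alone). The median was 0.77 (camera adjusted p = 0.00267, and adjusted p = 0.404 with an estimated correlation). For neutrophil markers, the median was 5.15 (camera adjusted p = 1.95e-13, and adjusted p = 0.0856 with an estimated correlation), and 14 of 14 were called higher and 0 lower (14 and 0 adjusted over the list alone). Of the monocyte markers, 12 of 13 tested members rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 2.00 (camera adjusted p = 1.02e-06, and adjusted p = 0.0722 with an estimated correlation). Chil3 rose by 6.89 ± 0.62. Of the fibroblast markers, 3 rose, 7 fell and 3 were not called (3 and 7 adjusted over the list alone). The median was -0.40 (camera adjusted p = 0.0788). The list was called with the replicate number as a block and without 6 h replicate 1 (adjusted p = 0.0475 and 0.0263, from 0.0205 to 0.603 over its alternatives). The collagen gene Col3a1 (-1.80 ± 0.33) and the proteoglycan Lum (-1.77 ± 0.19) fell most. Of the ventricular cardiomyocyte markers, the median was 0.024 (camera adjusted p = 0.955), with median, mean and test differing in sign, and 2 of 17 were called higher and 3 lower (2 and 3 adjusted over the list alone).

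At 6 h, 3714 genes were higher and 3460 lower than in sham, 1583 and 1362 by at least 2-fold, and 9081 genes had libraries that did not overlap (60.03%, with 10% by chance). From 3 h to 6 h, 2227 genes were higher and 1996 lower. Between these times Chil3 had 590 reads against 3, a ratio of 189 with a 95% exact counting interval from 64.3 to 919, and Saa3 (4.81 ± 0.75) and the nicotinamide riboside kinase Nmrk2 (4.40 ± 0.42) rose. Fosb (-6.02 ± 0.69), Fos (-3.49 ± 0.45) and Ikzf4 (-3.15 ± 0.44) fell.

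After 12 h, markers of monocytes and neutrophils and genes of matrix remodelling were still high. Cxcl5 had 2639 reads against 3, a ratio of 784 with a 95% exact counting interval from 268 to 3803, and Cxcl3 had 488 reads against 1, a ratio of 435 with a 95% exact counting interval from 77.7 to 17207. Arg1 had 1122 reads against 3, a ratio of 333 with a 95% exact counting interval from 114 to 1618 (arginase 1). Chil3, a chitinase-like protein of myeloid cells, rose from 0.0937 ± 0.0383 to 26.2 ± 6.39 CPM (8.01 ± 0.60), and Saa3 had 657 reads against 2, a ratio of 293 with a 95% exact counting interval from 80.7 to 2422. Cyp1a1 fell from 12.6 ± 14.3 to 0.361 ± 0.232 CPM (-5.11 ± 1.22), and Inmt (-3.91 ± 0.45), the uroplakin Upk3b (-3.63 ± 0.94) and the collagen gene Col6a6 (-3.55 ± 0.27) fell as well. The call of Cyp1a1 was lost with limma-voom, its adjusted p running from 1.35e-51 to 0.116 over its alternatives.

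Of the matrix remodelling genes, 19 of 22 tested members rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 2.01 (camera adjusted p = 4.85e-18, and adjusted p = 0.0338 with an estimated correlation). Spp1, which encodes osteopontin, rose by 6.52 ± 0.65, Timp1 by 5.29 ± 0.33 and tenascin Tnc by 3.89 ± 0.36. Among cytokines and adhesion molecules, 23 rose, 0 fell and 4 were not called (24 and 0 adjusted over the list alone). The median was 4.18 (camera adjusted p = 1.37e-24, and adjusted p = 0.0349 with an estimated correlation). The monocyte chemokine Ccl2 rose by 6.00 ± 0.53. Of the cardiac ion channel and calcium handling genes, the median was -0.87 (camera adjusted p = 2.45e-09, and adjusted p = 0.0617 with an estimated correlation), and 1 of 20 were called higher and 15 lower (1 and 17 adjusted over the list alone). Kcnj3 (-1.68 ± 0.19), Kcnd2 (-1.57 ± 0.17) and Pln (-1.27 ± 0.17) fell most. Of the fetal and wall stress genes, 10 of 13 tested members rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 1.60 (camera adjusted p = 7.15e-09, and adjusted p = 0.0646 with an estimated correlation). Ankrd1 (2.83 ± 0.23) and the natriuretic peptide Nppa (2.83 ± 0.35) led. Of metallothionein, acute phase and glucocorticoid-induced genes, 10 rose, 2 fell and 5 were not called (10 and 2 adjusted over the list alone). The median was 2.23 (camera adjusted p = 2.70e-09, and adjusted p = 0.0646 with an estimated correlation). Lcn2 rose by 5.57 ± 0.45. Serpina3m was at least 23.2-fold above sham, which left the median the same. Of the mitochondrially encoded protein genes, the median was -0.74 (camera adjusted p = 0.00645, and adjusted p = 0.413 with an estimated correlation), and 0 of 13 were called higher and 7 lower (0 and 7 adjusted over the list alone). The list was no longer called with duplicate reads removed (adjusted p = 0.0644, from 0.000430 to 0.413 over its alternatives). mt-Nd2 (-0.98 ± 0.21) and mt-Nd6 (-0.92 ± 0.25) fell most, with a mitochondrial share of 21.8% ± 1.90 and a median of -0.39 with duplicate reads removed.

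At 12 h, among immediate early genes, 11 of 34 tested members rose and 2 fell (12 and 3 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 0.00334, and adjusted p = 0.634 with an estimated correlation). Of the unfolded protein and integrated stress response genes, 7 rose, 1 fell and 15 were not called (7 and 1 adjusted over the list alone). The median was 0.54 (camera adjusted p = 0.0203, and adjusted p = 0.501 with an estimated correlation). Of the NRF2 targets, the median was 0.66 (camera adjusted p = 0.00479, and adjusted p = 0.404 with an estimated correlation), and 8 of 16 were called higher and 1 lower (9 and 1 adjusted over the list alone). Of the neutrophil markers, 14 of 14 tested members rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 4.48 (camera adjusted p = 2.93e-18, and adjusted p = 0.0427 with an estimated correlation). Clec4e rose by 5.42 ± 0.61. For monocyte markers, 12 rose, 0 fell and 1 was not called (12 and 0 adjusted over the list alone). The median was 2.19 (camera adjusted p = 8.39e-11, and adjusted p = 0.0338 with an estimated correlation). Plac8 (3.73 ± 0.63) and Ifitm6 (3.60 ± 0.66) followed Chil3. In the heat shock response, the median was 0.27 (camera adjusted p = 0.0994), and 5 of 18 were called higher and 0 lower (3 and 0 adjusted over the list alone). The list was called scaled by library totals, without sham replicate 1 and without 12 h replicate 1 (adjusted p = 0.0369, 0.0321 and 0.0277, from 0.0277 to 0.680 over its alternatives). Of the ventricular cardiomyocyte markers, 0 of 17 tested members rose and 4 fell (0 and 4 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.0628). The list was called without 12 h replicate 3 (adjusted p = 0.0254, from 0.0254 to 0.634 over its alternatives). The cardiac actin gene Actc1 (-0.85 ± 0.15) and Mybpc3, a sarcomere protein (-0.63 ± 0.13), fell.

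At 12 h, 2551 genes were higher and 2256 lower than in sham. Scaled by library totals, 4079 were higher and 1229 lower (76.8% against 53.1% higher), and the median of all genes shifted by 0.217. From 6 h to 12 h, 982 genes were higher and 1010 lower, or 1768 and 422 scaled by library totals (80.7% against 49.3% higher, with a shift of 0.166). The vessel growth factor Angpt1 (2.67 ± 0.27), Spp1 (2.64 ± 0.45) and Ky (2.52 ± 0.34) rose most, and Hspa1a (-4.53 ± 0.73), Hspa1b (-3.79 ± 0.78) and the deubiquitinase Otud1 (-3.64 ± 0.61) fell most. The count was 786 without 6 h replicate 2, 1140 without 12 h replicate 1 and 1186 without 12 h replicate 2.

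**Figure D2:**
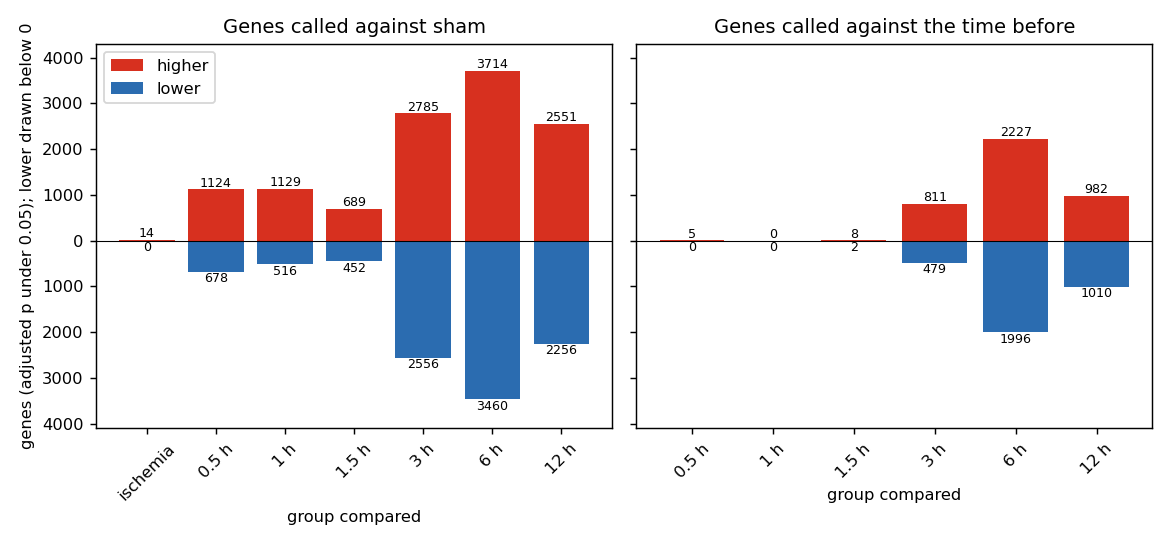
Number of genes called at each time against sham (left) and against the time before (right), with the group compared on the x axis and genes on the y axis, higher ones drawn above 0 and lower ones below. Calls against sham are most numerous at 6 h, with 3714 higher and 3460 lower.

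**Figure D3:**
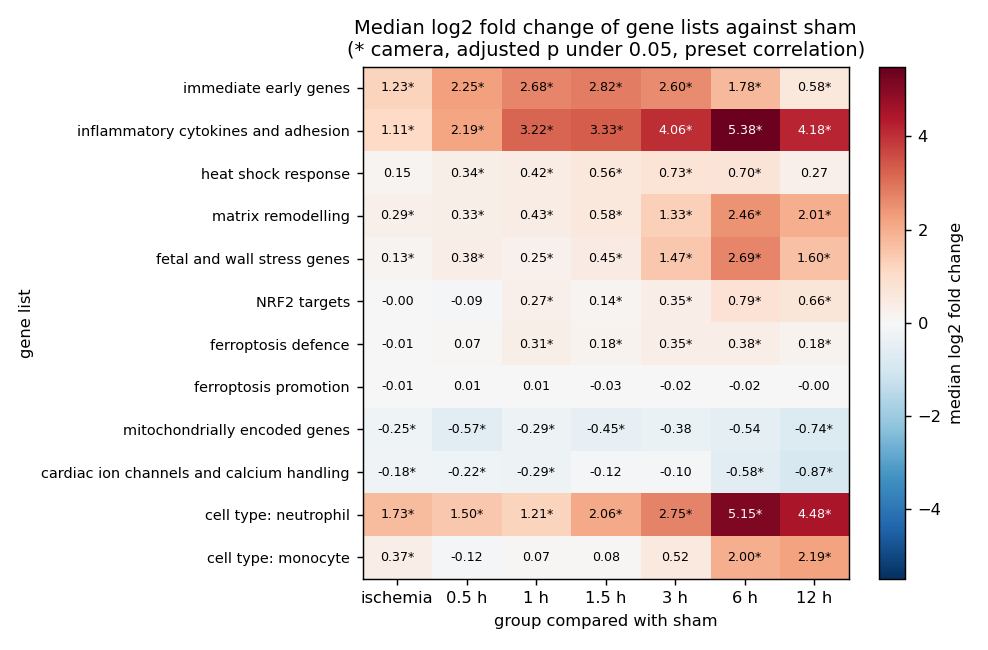
Median log2 fold change against sham of gene lists (y axis) in the 7 groups compared (x axis), with colour and number for the median and a star where camera's adjusted p with a preset correlation was under 0.05. The list of inflammatory cytokines and adhesion has its largest median, 5.38, at 6 h.

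The series title names ATF3, FANCD2 and cardiac ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation, and 9 genes were followed through every comparison for that reason. Atf3 (ENSMUSG00000026628; GRCm38 chromosome 1, 191170296 to 191218039, minus strand) rose against sham at each time from 0.5 h to 6 h, beside the rise in ischemia given above, from 8.47 ± 0.389 CPM in sham to 576 ± 131 CPM at 1.5 h. Its log2 fold change was 4.75 ± 0.56 at 0.5 h, 5.78 ± 0.58 at 1 h, 6.09 ± 0.59 at 1.5 h, 5.77 ± 0.58 at 3 h and 3.49 ± 0.54 at 6 h. At 12 h it was 0.96 ± 0.52 (adjusted p = 0.170, from 2.25e-08 to 0.628 over its alternatives), called only without a filter. It fell by 2.28 ± 0.48 from 3 h to 6 h (adjusted p = 0.00119) and by 2.54 ± 0.50 from 6 h to 12 h (adjusted p = 0.00168).

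Fancd2, a protein of the Fanconi anaemia DNA repair pathway (ENSMUSG00000034023; GRCm38 chromosome 6, 113531682 to 113597017, plus strand), had few reads, 23 over the 3 sham libraries and 67 over those of ischemia. Its group means lay between 0.341 and 1.41 CPM, and no comparison called it. Its log2 fold change against sham was 1.37 ± 0.71 in ischemia (adjusted p = 0.628) and -0.65 ± 0.83 at 6 h (adjusted p = 0.544). Its libraries of ischemia (1.27 to 1.48 CPM) and sham (0.449 to 0.720 CPM) did not overlap, as in 14.1% of genes (10% by chance). Of the measured genes of Fanconi anaemia and crosslink repair at 6 h, 2 rose, 5 fell and 10 were not called (2 and 4 adjusted over the list alone). The median was -0.46 (camera adjusted p = 0.322).

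Among ferroptosis genes, Ptgs2, a common marker of the process, rose in every group, by 3.31 ± 0.47 in ischemia and 4.80 ± 0.46 at 6 h (from 1.16 ± 0.518 to 31.8 ± 6.90 CPM). Hmox1 rose by 1.84 ± 0.45 at 1 h, 2.37 ± 0.45 at 1.5 h, 4.04 ± 0.47 at 3 h, 4.53 ± 0.47 at 6 h and 3.26 ± 0.46 at 12 h. Slc7a11, which imports cystine for glutathione, rose by 2.88 ± 0.61 at 3 h, 4.48 ± 0.57 at 6 h and 3.86 ± 0.58 at 12 h, from 0.211 ± 0.0649 CPM in sham to 4.86 ± 2.82 CPM at 6 h. Acsl4, which loads polyunsaturated fatty acids into phospholipids, was -0.44 ± 0.13 at 0.5 h and rose by 0.62 ± 0.13 at 3 h and 0.70 ± 0.13 at 6 h. Gpx4, the lipid hydroperoxide reductase, rose by 0.35 ± 0.13 and ferritin heavy chain Fth1 by 0.40 ± 0.15 at 3 h, but neither passed across the 8 groups (adjusted p = 0.0599 and 0.104). Gpx4 had like means at 1 h and 1.5 h (392 ± 93.1 and 387 ± 28.1 CPM, 387 ± 51.0 at 3 h). Gpx4 at 1 h (adjusted p = 0.0728, from 0.0131 to 0.431 over its alternatives) was called without 1 h replicate 2 (adjusted p = 0.0184) and under 4 other settings, and Fth1 at 6 h (adjusted p = 0.0550, from 0.00678 to 0.170) under 7. Tfrc, the transferrin receptor, fell by 1.80 ± 0.53 at 1 h and by 1.78 ± 0.53 at 12 h, with sham libraries spread from 103 to 386 CPM.

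Other calls against sham were made only under alternatives. Hmox1 at 0.5 h (1.16 ± 0.46, adjusted p = 0.0977) was called without a filter and with only 6 libraries (adjusted p = 2.52e-10 and 0.0278). Acsl4 at 12 h (0.32 ± 0.13, adjusted p = 0.0626) was called with library totals, the clock score, only 6 libraries and without 12 h replicate 1 (adjusted p = 0.00425, 0.0394, 0.0438 and 0.0352). Tfrc was called without a filter at 0.5, 3 and 6 h (adjusted p = 0.0180, 1.33e-07 and 1.21e-15), and at 6 h also with only 6 libraries or without sham or 6 h replicate 3 (adjusted p = 0.0482, 0.0186 and 0.0260). Its libraries at 0.5, 3 and 6 h (158 to 223, 50.5 to 215 and 55.8 to 163 CPM) overlapped those of sham (103 to 386 CPM). The small values without a filter therefore do not measure the spread between libraries. Gpx4 at 0.5 h and Fth1 at 1 h and 12 h were called with library totals (adjusted p = 0.0249, 0.0497 and 0.0412), and Gpx4 at 0.5 h and both genes at 1.5 h with only 6 libraries (adjusted p = 0.0278, 0.0170 and 0.0121). The call of Acsl4 at 0.5 h was lost without sham replicates 1, 2 or 3 or 0.5 h replicates 1, 2 or 3 (adjusted p = 0.0780, 0.0602, 0.118, 0.150, 0.0681 and 0.0576), that of Gpx4 at 3 h without sham replicates 1, 2 or 3 or 3 h replicates 2 or 3 (adjusted p = 0.130, 0.0945, 0.0612, 0.194 and 0.0594), that of Fth1 at 3 h without sham replicates 1, 2 or 3 or 3 h replicates 2 or 3 (adjusted p = 0.0769, 0.0566, 0.116, 0.130 and 0.0672), that of Tfrc at 1 h without sham replicates 1 or 2 or 1 h replicates 1 or 3 (adjusted p = 0.156, 0.0711, 0.138 and 0.0727), that of Tfrc at 12 h without sham replicate 1 or 12 h replicates 1 or 2 (adjusted p = 0.0823, 0.0570 and 0.0661) and that of Hmox1 at 1 h without sham replicate 2 or 1 h replicate 1 (adjusted p = 0.0541 and 0.0556). Their adjusted p ran from 0.0123 to 0.151 for Acsl4, from 0.00871 to 0.194 for Gpx4, from 0.0148 to 0.130 for Fth1, from 1.45e-32 to 0.156 for Tfrc at 1 h, from 4.28e-31 to 0.0823 for Tfrc at 12 h and from 2.20e-27 to 0.0556 for Hmox1 over the alternatives. Of the ferroptosis defence genes at 6 h, the median was 0.38 (camera adjusted p = 0.00359, and adjusted p = 0.323 with an estimated correlation), and 11 of 21 were called higher and 2 lower (12 and 2 adjusted over the list alone). At 12 h, of the same list, 7 of 21 tested members rose and 3 fell (7 and 3 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.0193, and adjusted p = 0.445 with an estimated correlation). Of the genes that promote ferroptosis at 6 h, 8 rose, 10 fell and 7 were not called (8 and 11 adjusted over the list alone). The median was -0.017 (camera adjusted p = 0.699), with median, mean and test differing in sign.

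**Figure D4:**
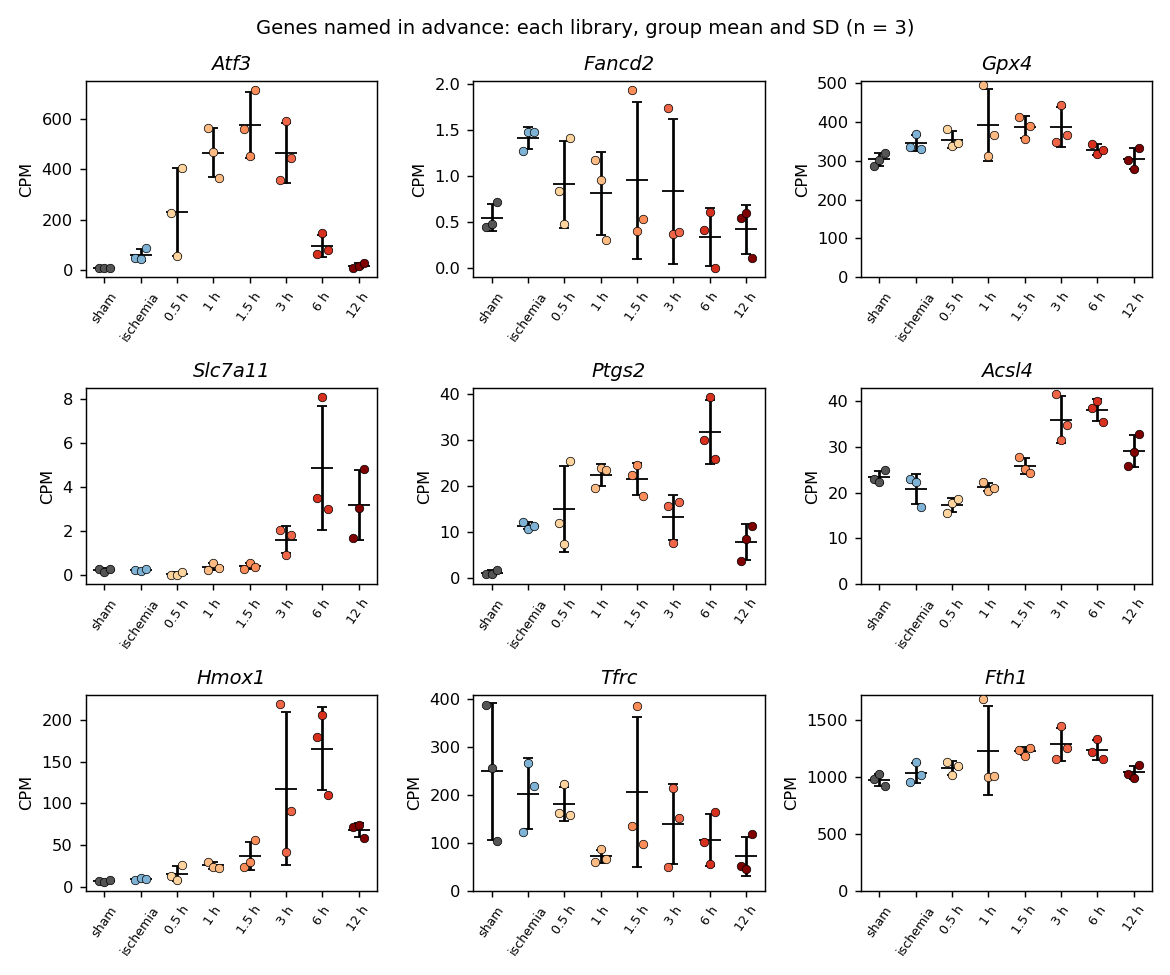
Expression of 9 genes named in advance, with the group on the x axis, CPM on a linear y axis, 1 point per library and the bar for the group mean with SD (n = 3). Atf3 reaches 576 CPM at 1.5 h from 8.47 CPM in sham, and Fancd2 stays between 0.341 and 1.41 CPM in its group means.

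Across all 8 groups together, 9726 of 15128 genes changed. For 4098 of these the largest difference from sham fell at 6 h, for 2235 at 3 h, for 1744 at 12 h, and for 75, 593, 567 and 414 in ischemia and at 0.5, 1 and 1.5 h.

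Clock genes differed between libraries of 1 group as well as between groups. Arntl, an activator of the clock, was 30.6, 23.2 and 2.48 CPM in sham replicates 1, 2 and 3, and Dbp, an output gene of the opposite phase, was 5.65, 13.2 and 48.5 CPM. Of the circadian clock genes at 1.5 h against sham, the median was 0.23 (camera adjusted p = 0.000986, and adjusted p = 0.0904 with an estimated correlation), and 5 of 18 were called higher and 0 lower (7 and 0 adjusted over the list alone). Nfil3 (2.35 ± 0.34) and Bhlhe40 (2.12 ± 0.31) led. At 3 h, of the clock genes, 8 of 18 tested members rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 0.00755, and adjusted p = 0.191 with an estimated correlation).

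**Figure D5:**
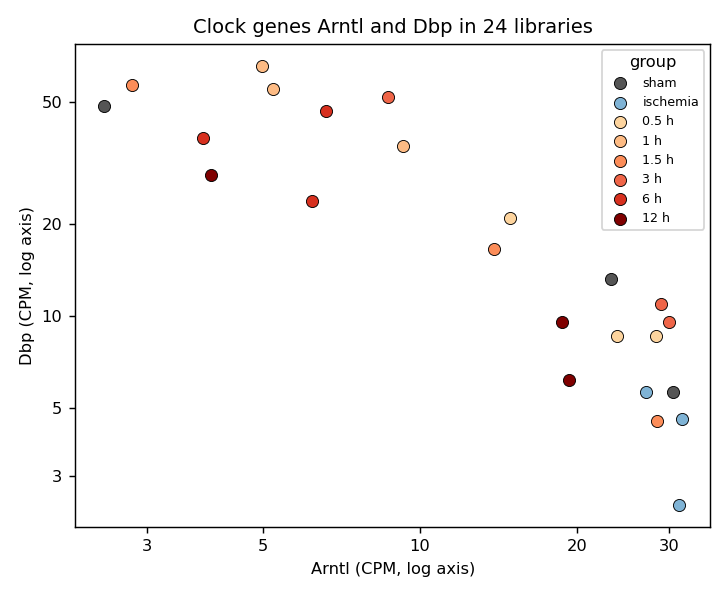
Arntl (x axis) and Dbp (y axis) in CPM on log axes, 1 point per library and colour for the group. Sham replicate 3 lies opposite the other sham libraries.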

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

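In the part that follows, the tests of a label exchange and of the cardiomyocyte and nuclear gene medians were chosen after the results were seen. For 5 of the 9 genes followed through every comparison, the level differed between neighbouring times. Atf3 was -2.28 ± 0.48 at 6 h relative to 3 h and -2.54 ± 0.50 at 12 h relative to 6 h. Slc7a11 was 2.06 ± 0.55 at 3 h relative to 1.5 h and 1.60 ± 0.43 at 6 h relative to 3 h. Ptgs2 was 1.26 ± 0.34 at 6 h relative to 3 h and -2.03 ± 0.35 at 12 h relative to 6 h. Acsl4 was 0.48 ± 0.13 at 3 h relative to 1.5 h and -0.38 ± 0.13 at 12 h relative to 6 h, and Hmox1 was 1.67 ± 0.41 and -1.27 ± 0.40 in the same steps. From 1.5 h to 3 h, the call of Slc7a11 was lost without 1.5 h replicates 1 or 3 or 3 h replicates 1 or 3 (adjusted p = 0.0942, 0.0637, 0.0862 and 0.0769), that of Acsl4 without 1.5 h replicates 2 or 3 or 3 h replicates 1 or 3 (adjusted p = 0.0852, 0.0710, 0.126 and 0.0540) and that of Hmox1 without 1.5 h replicates 1 or 2 or 3 h replicate 1 (adjusted p = 0.0754, 0.0724 and 0.171). The range of adjusted p was from 0.000920 to 0.0942 for Slc7a11, from 0.00837 to 0.126 for Acsl4 and from 1.27e-26 to 0.171 for Hmox1 over the alternatives. From 3 h to 6 h, the call of Slc7a11 was lost without 6 h replicate 2 (adjusted p = 0.116) and that of Ptgs2 without 3 h replicate 2 (adjusted p = 0.0562). Over the alternatives, adjusted p ran from 0.000258 to 0.116 for Slc7a11 and from 1.50e-11 to 0.0562 for Ptgs2. From 6 h to 12 h, the call of Acsl4 was lost without 6 h replicates 1, 2 or 3 or 12 h replicates 1 or 2 (adjusted p = 0.10004, 0.175, 0.0524, 0.162 and 0.104) and that of Hmox1 without 6 h replicates 1 or 2 or 12 h replicates 1, 2 or 3 (adjusted p = 0.0773, 0.156, 0.0821, 0.0786 and 0.0990). Their adjusted p ran from 0.0232 to 0.296 for Acsl4 and from 3.72e-16 to 0.156 for Hmox1 over the alternatives.

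Among genes that passed the filter only with multiply mapped reads included, 289 in all, 43 were higher and 48 lower at 6 h than in sham. In ischemia 0 of them were called with edgeR.

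Ischemia replicate 3 lay apart from the other ischemia libraries, and 1156 genes differed between 0.5 h and ischemia without it against 5 with it. A label exchange with a reperfused library stays open. In Hspa1a and Hspa1b, among the 5 called genes, the lowest reperfused library up to 6 h exceeded ischemia replicate 3 by 10.4 and 17.5 times. But 0.5 h replicate 2 was close to it by chi-square per degree of freedom (8.95, ischemia replicates 1 and 2: 74.1 and 64.7). Mitochondrial reads are argued against by 1146 calls without replicate 3 and 5 with it, mitochondrial genes left out. Duplicate reads are argued against by 1375 and 15 calls with duplicates removed. A difference in the surgery or in the time until tissue was taken stays open, and no biological explanation was tested.

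Clock genes differed within groups. After group means were removed, the median of the 6 correlations of Npas2 and Clock with Per3, Tef and Hlf was -0.781 (one-sided permutation p = 0.000400, 10000 permutations), a pattern that different times of day at collection may produce. The mitochondrial share of a library correlated with the clock score at r = -0.171 (permutation p = 0.321, rho = -0.247 with permutation p = 0.284, 95% interval of r from -0.602 to 0.337, -0.0858 without 2 libraries). The duplicate share gave r = -0.295 (permutation p = 0.124, rho = -0.365 with permutation p = 0.104, interval from -0.679 to 0.217, -0.260 without 2 libraries). With adjusted p of 0.321 and 0.204 over 3 relations, and intervals this wide, these shares stay open, although the median correlation was -0.807 and -0.783 after they were removed.

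The 13 mitochondrially encoded protein genes had medians below 0 in the 7 comparisons with sham. At 0.5 h, a smaller share of cardiomyocyte RNA is argued against by the median of the ventricular cardiomyocyte markers, 0.19, and lower expression of all oxidative phosphorylation genes by that of the nuclear genes, 0.20, where the mitochondrial median was -0.57. At 12 h the medians were -0.21, -0.15 and -0.74, so that both explanations stay open there for part of the fall. Saturation by duplicate reads could account for part of the pattern. With duplicates removed, the medians were -0.090 at 0.5 h, 0.095 at 1 h, -0.041 at 6 h and -0.39 at 12 h, but removal itself caps genes covered this deeply, so the explanation cannot be told apart from a fall in these transcripts.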

How the results depend on the processing

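Of the alternatives, only the clock score came after the data were seen. No call of a named gene reversed direction under any. The larger side of the calls turned at 12 h against 6 h, from 982 higher and 1010 lower to 1768 and 422 with library totals, 1163 and 1144 with duplicates removed and 313 and 261 with a minimum change. It also turned at 6 h against 3 h, from 2227 and 1996 to 709 and 753 with a minimum change, and at 1.5 h against 1 h, from 8 and 2 to 0 and 1 with only 6 libraries. With the DESeq2 Wald test, 48 genes were called in ischemia against sham, 62 at 0.5 h against ischemia and 70 at 1.5 h against 1 h, where edgeR called 14, 5 and 10. Limma-voom called 3 in ischemia and 2 at 1.5 h against 1 h. Without a filter the counts were 289 in ischemia against sham, 329 at 0.5 h against ischemia, 159 at 1 h against 0.5 h and 357 at 1.5 h against 1 h. Only the 6 libraries compared gave 29 in ischemia, 3937 at 0.5 h and 2062 at 1.5 h against sham, 0 at 0.5 h against ischemia, 1 at 1.5 h against 1 h, 679 at 3 h against 1.5 h and 2765 at 6 h against 3 h. A minimum absolute log2 fold change of 1 left 442, 525, 567, 1846, 2945 and 1632 genes at 0.5, 1, 1.5, 3, 6 and 12 h against sham, 378 at 3 h against 1.5 h, 1462 at 6 h against 3 h and 574 at 12 h against 6 h, by its own construction. At 0.5 h against ischemia, 15 genes were called with duplicates removed and 8 with multiply mapped reads. At 1.5 h against 1 h, 2 were called with library totals and 3 with the clock score. The other counts under these settings and under DESeq2 size factors, a filter of 1 CPM in 3 libraries and mitochondrial genes left out lay within 1.5 times of the reported ones. The cause was not tested for these differences between tools, filters and scalings.

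Leaving out each library in turn gave 5 to 39 genes in ischemia, 603 to 1093 at 0.5 h, 559 to 1669 at 1 h and 503 to 1041 at 1.5 h against sham. Between neighbouring times it gave 2 to 1156 at 0.5 h against ischemia, 0 to 3 at 1 h against 0.5 h, 0 to 20 at 1.5 h against 1 h, 525 to 1751 at 3 h against 1.5 h and 786 to 1792 at 12 h against 6 h. Counts at 3, 6 and 12 h against sham, at 6 h against 3 h and across the 8 groups stayed within 1.5 times. Among the values of named genes in single comparisons, calls were lost in 54 with limma-voom, 40 with library totals, 33 with the clock score, 32 with duplicates removed, 30 with only 6 libraries, 16 without a filter and 8 with DESeq2, and in 669 of the fits that left out 1 library, against 3740 of those fits on the same side of the threshold. Of 109 calls of gene lists, 20 were also made with an estimated correlation, and fry, which does not compare a list with other genes, called 112.

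The replicate numbers of the labels did not pair the libraries. Deviations from the group means correlated by -0.00735 on average between libraries of the same number (84 pairs, from -0.179 to 0.199) and by 0.00359 between the others (168 pairs), and 5 of 24 libraries were closest to their own number. With the replicate block, 12 genes were called at 0.5 h against ischemia, 18 of the named calls were lost and 2 lists gained one, and the other counts lay within 1.5 times. Depth widened the intervals of ratios to 1 to 3 reads, such as that of Il6 in ischemia, from 25.6 to 5765. For Fancd2, depth was not told apart from spread between libraries.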

Other observations

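The test of Tfrc against the clock score was chosen after its result was seen, and the other tests of this part were fixed earlier. Of the interferon response genes at 12 h, 0 rose, 5 fell and 18 were not called (0 and 5 adjusted over the list alone). The median was -0.41 (camera adjusted p = 0.0241, and adjusted p = 0.685 with an estimated correlation). The list was no longer called without 12 h replicate 3 (adjusted p = 0.230, from 0.000461 to 0.685 over its alternatives).

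The genes that rose at least 2-fold by 0.5 h had short gene bodies. The median span of 323 of them was 3.87 kb, against 15.9 kb for 725 genes that rose at least 2-fold at 12 h without a call at 0.5 h (permutation p = 1e-05, the smallest these permutations can give) and 21.4 kb for all tested genes with a span. In 10000 random sets matched on expression the median lay between 16.7 and 24.02 kb in 95% of sets, and 0 sets were as short. Of the early genes 23.5% had a single exon, against 5.52% of the later ones. The time to transcribe a gene may set part of this order, tested only through length. Gene class was not matched and stays open.

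One hypothesis is that Tfrc follows the clock genes. After group means were removed, its log2 CPM correlated with the clock score over 24 libraries at r = 0.462 (permutation p = 0.136, adjusted p = 0.204 over 3 relations; rho = 0.402, permutation p = 0.148, adjusted p = 0.222), and r was 0.334 without the 2 libraries farthest from the median score, which leaves the question undecided. With the clock score as covariate, the fall at 1 h went from -1.80 ± 0.53 to -1.26 ± 0.51 and lost its call (adjusted p = 0.127), since the change shrank while its error stayed similar, and that at 12 h went from -1.78 ± 0.53 to -1.52 ± 0.49 and kept it (adjusted p = 0.0189).

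Other divisions of the same libraries were tested as well. Across the 8 groups, 1 of 100 divisions, the real one, reached 9726 genes. The highest other gave 698, so chance is unlikely if libraries are independent. Groups of 3 against 3 allow only 10 divisions, too few for a share under 0.05. Against sham, the real counts were 14, 1802, 1645, 1141, 5341, 7174 and 4807 from ischemia to 12 h, and the highest other was 2 at 3 h and 0 in the rest. Between neighbouring times the real and highest other counts were 5 and 28 at 0.5 h, 0 and 1 at 1 h, 10 and 0 at 1.5 h, 1290 and 2 at 3 h, 4223 and 11 at 6 h, and 1992 and 33 at 12 h. The division with 28 set ischemia replicates 1 and 2 with 0.5 h replicate 2 apart from the other 3 libraries, which points to a structure of the samples.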
